A study of Mus musculus with 8 samples.

How the data were processed

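Polyadenylated RNA of mouse embryonic stem cells with a floxed Htatsf1 gene and CreERT2, grown on mouse embryonic fibroblasts, was sequenced as paired ends after ethanol or tamoxifen for 48 h or 72 h, per the labels' protocols. Groups and replicate numbers came from the labels, giving 4 groups of 2 libraries. Each library has a table of FPKM per gene with a confidence interval and a status, as deposited by the authors, in the layout of Cufflinks. Per the submitters' processing notes, the tools were BWA 0.6.1, TopHat 1.4.1, Cufflinks 1.3.0, HTSeq and DESeq, with genome build mm9, and neither their roles nor the last 2 versions are given in the sources used here.

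The authors also deposited 2 tables of comparisons, 1 for each time. Their group means are a signal of counts divided by size factors, pooled over the libraries of a group, per the file headers. Their log2 fold changes, as deposited, are ethanol over tamoxifen, which a recomputation from the group means showed, so the sign was turned here. Their p-values and adjusted p-values are the authors' own and were described, not retested.

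Every library table holds 20789 distinct entries for 20461 gene identifiers. Entries whose status was not OK in at least 1 library (209) were left out and 1 entry was kept per identifier, that of highest mean FPKM, which left 20388. Genes with an FPKM of at least 1 in at least 2 of the 8 libraries were tested (11867). The FPKM values were used as deposited, without rescaling, as log2(FPKM + 1). An exact 0 can be a failed estimate in such files, as for Sox2. Positions are those of the files on mm9. Of 7876 genes whose length in the files lay within 2 bases of that in a GRCm38 gene table, 7023 had an end minus start equal to the full length, so starts count from 0 in the files and 1 was added.

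The files hold no read counts, and depth was estimated from them. The distance from a value to its bound, taken as 2 SD of a Poisson count, gives the fragments behind a value, and for genes with 1 start site and up to 20 fragments between 90.9% and 91.9% of these were whole within 0.02. Their sums per library ran from 8.99 to 16.8 M, and cover counting error only. Within each group the squared difference of the 2 libraries over genes with at least 50 implied fragments in both was 1.80 to 3.03 times the counting variance, so no pair was 1 library deposited in duplicate. The correlation of log2(FPKM + 1) within groups was 0.995 to 0.997. On principal components of the tested genes the first, with 62.3% of the variance, parted 48 h from 72 h, and the second, with 24.3%, parted tamoxifen from ethanol.

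One limma fit (R 4.3.3, limma 3.58.1, statmod 1.5.0) over all 8 libraries with a mean for each group gave 4 residual degrees of freedom. The eBayes step used a mean trend, tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes tested within each of 4 contrasts: tamoxifen against ethanol at 48 h and at 72 h, the difference of these changes, and ethanol 72 h against ethanol 48 h. A gene was called at an adjusted p of 0.05. The 21 gene lists were tested with camera (preset inter-gene correlation 0.01, adjusted over the lists within a contrast), with an estimated correlation beside it. List counts use the adjustment over all genes. Beside most, but not all, of them stand counts adjusted over the list alone. With an estimated correlation the calls of the p53 list at both times and of cholesterol synthesis at 72 h held, and no other list call of tamoxifen against ethanol or of the difference did. That form of camera also rests on the 4 residual degrees of freedom, so its larger p-values do not measure correlation alone. For cholesterol synthesis at 72 h the estimated correlation was -0.015, below the preset, yet camera's unadjusted p went from 1.78e-07 to 0.00441. For the trophoblast list at 48 h (-0.046) it went from 0.0193 to 0.0701. The roast-type test fry asks whether a set moves one way or, in its mixed form, either way, without comparing it with other genes.

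The design, lists, the rule for named genes and the alternatives of the gene counts, named genes and set tests were fixed before the data were examined, while the comparison with the fibroblast median and the alternatives of the list counts were added later. The rule took, at 48 h and 72 h, Htatsf1, the 5 largest rises and 5 largest falls among called genes whose 2 tamoxifen libraries lay on one side of both ethanol libraries, and the 2 members of smallest p from each list past the set test and always from the core, naive and formative pluripotency, ribosomal protein, ribosome biogenesis, p53 and fibroblast lists. For the difference it took the 3 largest each way. Uncharacterised genes and small RNAs were left out. It gave 34, 32 and 6 genes. Any other gene named here was chosen after its values were seen, among them Rbmx, Fhl1 and Sox2.

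The fit was tested on simulated data made from the ethanol group means of the 11867 genes, with 200 genes changed in each of 20 runs. Spreads were drawn from the prior that limma had fitted, and noise was independent between genes, so the assumptions of the fit held by design. Fewer genes were changed than the 1466 and 4572 called at 48 h and 72 h, so recovery in the data may differ. At 48 h 23.7% of genes changed 1.25-fold, 78.5% changed 1.5-fold and 98.3% changed 2-fold were recovered, and at 72 h 26.0%, 77.5% and 98.6%, with 6.8 and 7 false calls per run. Both times carried the same change there, so no difference was simulated and 0 were called. In further runs, added later, with the change at 72 h alone, the test of the difference recovered 3.66% at 1.25-fold, 45.3% at 1.5-fold and 89.5% at 2-fold, with 5.2 false calls per run. Of 20 simulated lists of 39 genes with 20 changed, all of them raised, 20 were found at 48 h, and 0 of 20 unchanged lists. Found here meant an unadjusted camera p under 0.05, while lists of the data were called at a p adjusted over 21 lists. Genes of the simulated lists were uncorrelated, while the estimated correlation in the data was 0.43 for the fibroblast list and 0.42 for cytoplasmic ribosomal proteins. The simulated lists therefore cannot show how often lists of correlated genes are called falsely. Alternatives were other pseudocounts, filters, scalings and spread priors, the libraries of a time point alone, replicate blocks, a 2-fold threshold, leaving out each library, and other set tests. Plots were drawn with matplotlib 3.10.9.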

Results

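RNA was sequenced from mouse embryonic stem cells that carry a floxed Htatsf1 gene and CreERT2, a recombinase that tamoxifen activates, so that tamoxifen deletes the gene. HTATSF1 is an RNA-binding protein known to associate with the U2 snRNP of the spliceosome. The stem cells were grown on a layer of mouse embryonic fibroblasts, which also contribute RNA. Cells received tamoxifen or ethanol, the vehicle, for 48 h or 72 h, with 2 libraries in each of the 4 groups and 8 in all. The fragments implied by the intervals around the deposited FPKM values summed to between 8.99 M in tamoxifen 48 h replicate 1 and 16.8 M in tamoxifen 72 h replicate 1. The median tested gene rested on 260 to 531 of them. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. All fold changes below are on the scale of log2(FPKM + 1), which understates changes of genes with low values.

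The targeted gene was examined first. Htatsf1, on chromosome X from 54306747 to 54320359 of mm9, stood at 22.3 ± 0.92 FPKM (SD, n = 2) in ethanol and 3.95 ± 0.25 FPKM (SD, n = 2) in tamoxifen at 48 h. At 72 h it stood at 22.7 ± 0.02 FPKM (SD, n = 2) in ethanol and 4.38 ± 0.36 FPKM (SD, n = 2) in tamoxifen. The remaining signal was 17.7% of ethanol at 48 h and 19.2% at 72 h. Feeder RNA may be part of this signal, so the share left in the stem cells alone was not measured. Both falls passed the limma test, with log2 changes of -2.24 ± 0.08 (SE, adjusted p = 4.06e-07) and -2.14 ± 0.08 (SE, adjusted p = 1.56e-07). The difference between the 2 times did not pass (adjusted p = 0.683). Of 5 tested genes listed as neighbours of Htatsf1 on chromosome X, 1 fell at 48 h (Rbmx, log2 change -0.42) and 1 rose at 72 h (Fhl1, 0.26), and the list did not pass camera at either time (adjusted p = 0.794 and 0.753). For change in either direction limma's fry gave it unadjusted p = 0.000169 and 0.015.

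**Figure D1:**
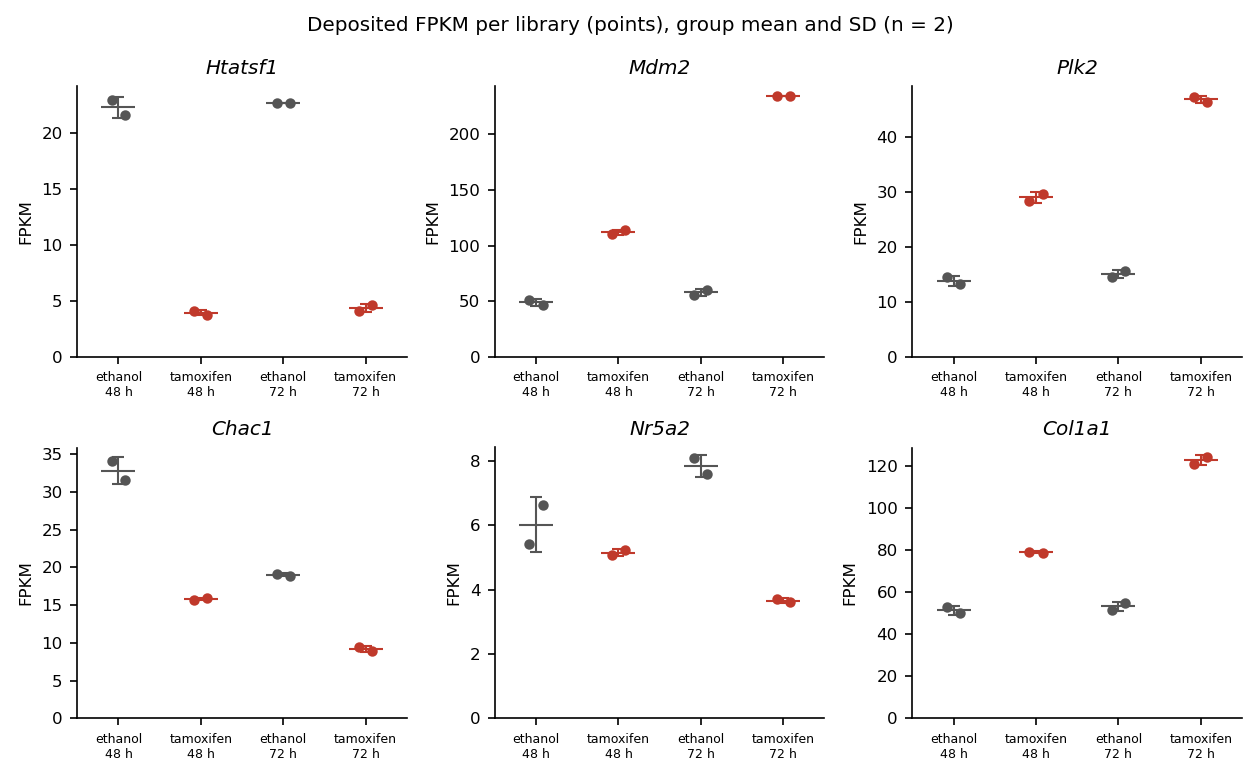
Deposited FPKM of 6 genes in the 8 libraries, by treatment and time. Points are single libraries, horizontal bars the group mean and vertical bars the SD (n = 2). Htatsf1 stood near 22 FPKM in ethanol and 4 FPKM in tamoxifen, while Mdm2 rose from 57.9 to 234 FPKM and Nr5a2 fell from 7.85 to 3.66 FPKM at 72 h.

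The 48 h comparison asked which messenger RNAs had changed at the earlier time after deletion was induced. Targets of the transcription factor p53 were higher: of 39 tested members of that list 30 rose and 0 fell (33 and 0 adjusted over the list alone), with a median log2 change of 0.47. Mdm2, on chromosome 10 from 117125961 to 117147772 of mm9, encodes the ubiquitin ligase that limits p53. It rose from 48.9 ± 2.76 to 112 ± 2.41 FPKM (SD, n = 2 each, log2 change 1.18 ± 0.06 SE, adjusted p = 4.87e-06). Trp53inp1 rose from 35.7 ± 1.61 to 79.2 ± 3.72 FPKM (1.13 ± 0.06 SE, adjusted p = 4.87e-06). The list passed camera's set test with the preset correlation (adjusted p = 6.76e-26) and with an estimated correlation (adjusted p = 0.0269). Genes of the stress response run by ATF4 and of the unfolded protein response were lower, with 13 of 29 tested members falling and 1 rising (14 and 2 adjusted over the list alone). Chac1, on chromosome 2 from 119176978 to 119180062, encodes a glutathione-degrading enzyme and fell from 32.9 ± 1.76 to 15.8 ± 0.14 FPKM (-1.01 ± 0.07 SE, adjusted p = 2.09e-05). Stc2, a secreted glycoprotein, fell by 1.02 on the log2 scale (SE 0.13, adjusted p = 0.00117). That list had an adjusted p = 4.65e-08 with the preset correlation and an adjusted p = 0.129 with an estimated correlation. Its count of falls was 6 without ethanol replicate 1, 8 without ethanol replicate 2 and 8 without tamoxifen replicate 2.

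Markers of fibroblasts, the cells of the feeder layer, were also higher at 48 h, in the same libraries in which the p53 targets rose. Of 34 tested members 32 rose and 0 fell (34 and 0 adjusted over the list alone), with a median log2 change of 0.52. Thbs1, which encodes thrombospondin, rose from 116 ± 1.32 to 182 ± 0.41 FPKM (0.65 ± 0.05 SE, adjusted p = 8.8e-05). Col1a1, a chain of type I collagen on chromosome 11 from 94797584 to 94813170, rose from 51.5 ± 2.11 to 79.0 ± 0.49 FPKM (0.61 ± 0.05 SE, adjusted p = 0.000181). The list had an adjusted p = 3.9e-27 with the preset correlation and an adjusted p = 0.129 with an estimated correlation. Of 11 tested primitive endoderm genes 6 rose and 0 fell (6 and 1 adjusted over the list alone). They were led by the basement membrane collagens Col4a1 (0.61 ± 0.06 SE, adjusted p = 0.000392) and Col4a2 (0.62 ± 0.08 SE, adjusted p = 0.00183), which fibroblasts also make. The list had an adjusted p = 0.000975, and an adjusted p = 0.21 with an estimated correlation. Without ethanol replicate 2 the count of fibroblast genes that rose was 21, and without ethanol replicate 1, ethanol replicate 2 or tamoxifen replicate 2 the count of primitive endoderm genes was 3.

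Few genes of the pluripotency lists passed at 48 h. In the naive pluripotency list 1 of 20 tested genes rose (Tbx3, 0.47 ± 0.09 SE, adjusted p = 0.00843) and 0 fell, the same counts as adjusted over the list alone, and Stat3 stood at -0.17 (adjusted p = 0.104). Of 13 tested core pluripotency genes 1 fell (Tdgf1, -0.21 ± 0.06 SE, adjusted p = 0.0464) and 0 rose (0 and 0 adjusted over the list alone), and Dppa2 stood at 0.17 (adjusted p = 0.11). Of 19 genes of the formative and primed epiblast 1 rose and 1 fell (1 and 3 adjusted over the list alone). Nodal, a ligand of the TGF-beta family, rose from 21.6 ± 0.70 to 36.0 ± 1.09 FPKM (0.71 ± 0.06 SE, adjusted p = 0.000103). Dnmt3b, a DNA methyltransferase, fell from 238 ± 2.58 to 188 ± 4.74 FPKM (-0.34 ± 0.07 SE, adjusted p = 0.0124). In the 4 libraries of 48 h alone 1 naive gene fell. These 3 lists did not pass camera at 48 h (adjusted p = 0.794, 0.499 and 0.888), while fry, for change in either direction, gave unadjusted p = 0.00441, 2.35e-05 and 1.04e-06. Tbx3 lost its call without ethanol replicate 2 or tamoxifen replicate 2 (adjusted p = 0.0756 and 0.0509), and Dnmt3b without ethanol replicate 1, ethanol replicate 2 or tamoxifen replicate 1 (adjusted p = 0.0857, 0.0765 and 0.0749). Tdgf1 lost its call without any of 6 libraries (adjusted p up to 0.269), and with all of them after quantile normalization (-0.11, adjusted p = 0.214), without the filter on low values (adjusted p = 0.0989) and without the trend (adjusted p = 0.102).

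Most genes of the translation apparatus did not pass at 48 h. Among 73 tested genes of ribosome biogenesis 9 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.10. Dimt1, an 18S ribosomal RNA methyltransferase, stood at -0.46 ± 0.09 SE (adjusted p = 0.0105) and Npm3 at -0.34 ± 0.07 SE (adjusted p = 0.011). Of 81 cytoplasmic ribosomal protein genes 2 fell, Rpl22l1 (-0.58 ± 0.08 SE, adjusted p = 0.00166) and Rpl27 (-0.39 ± 0.08 SE, adjusted p = 0.0088), and 79 did not pass, the same counts as adjusted over the list alone. Of 75 mitochondrial ribosomal protein genes 12 fell and 0 rose (12 and 1 adjusted over the list alone), Mrpl55 at -0.44 ± 0.07 SE (adjusted p = 0.00256) and Mrps14 at -0.35 ± 0.05 SE (adjusted p = 0.0036). These 3 lists had adjusted p = 1.78e-05, 0.000263 and 0.000269 with the preset correlation, and with an estimated correlation an adjusted p = 0.129, 0.618 and 0.247. Many ribosomal protein genes have near-identical processed pseudogenes, so their FPKM values are uncertain. The ribosome biogenesis count of falls was 17 after median-ratio scaling, 5 without the filter on low values and 4 without the trend. It was 1 without ethanol replicate 1, 0 without ethanol replicate 2, 4 without tamoxifen replicate 1 and 2 without tamoxifen replicate 2.

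The cholesterol synthesis list had 3 of 24 members lower at 48 h (3 adjusted over the list alone), among them Sc4mol (-0.37 ± 0.10 SE, adjusted p = 0.0306) and Acat2 (-0.21 ± 0.05 SE, adjusted p = 0.033). The glycolysis list had 3 of 22 lower and 1 higher (4 and 1 adjusted over the list alone), among them Pdk1, a kinase that restrains pyruvate dehydrogenase (chromosome 2 from 71711329 to 71741915, -0.54 ± 0.06 SE, adjusted p = 0.000814), and Pfkp (-0.24 ± 0.06 SE, adjusted p = 0.0362). Their adjusted p was 0.00427 and 0.00266 with the preset correlation, and with an estimated correlation the adjusted p was 0.129 and 0.387. The trophoblast list had 2 of 11 members higher (4 adjusted over the list alone), Tfap2c (0.38 ± 0.07 SE, adjusted p = 0.00709) and Krt8 (0.20 ± 0.06 SE, adjusted p = 0.0477). That list had an adjusted p = 0.0368 and an adjusted p = 0.21 with an estimated correlation. Of 7 tested neuroectoderm genes 0 passed (0 adjusted over the list alone), Nes at -0.22 (adjusted p = 0.089) and Sox11 at -0.19 (adjusted p = 0.0893). The list had an adjusted p = 0.029, and an adjusted p = 0.363 with an estimated correlation. When single libraries were left out, Rpl27, Dimt1, Npm3, Sc4mol, Acat2, Pfkp, Tfap2c and Krt8 lost their calls at 48 h, with adjusted p up to 0.0705, 0.093, 0.0856, 0.184, 0.155, 0.224, 0.066 and 0.222. With all libraries kept, Krt8, Acat2 and Pfkp also lost theirs without the trend (adjusted p = 0.0871, 0.0699 and 0.0758) and after quantile normalization (adjusted p = 0.0858, 0.0554 and 0.0505). Without the filter on low values Krt8, Sc4mol and Pfkp did (adjusted p = 0.0544, 0.0865 and 0.0622), and Sc4mol without the trend (adjusted p = 0.0677). Krt8 also did after median-ratio scaling, with a pseudocount of 5 and in the 4 libraries of 48 h alone (adjusted p = 0.0833, 0.0546 and 0.0671). The cholesterol synthesis count was 5 after median-ratio scaling, 1 without the filter and 0 without the trend, and the glycolysis count 1 without the filter and 1 without the trend. The cholesterol synthesis count was 0 without ethanol replicate 1, ethanol replicate 2 or tamoxifen replicate 2 and 1 without tamoxifen replicate 1, and the glycolysis count was 1 without any 1 of these 4.

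Across all 11867 genes tested with limma at 48 h, 935 rose and 531 fell at an adjusted p of 0.05, and 13 rose and 3 fell by at least 2-fold. The largest rises among named genes were Neurod1, a neural transcription factor on chromosome 2 from 79292798 to 79296793 (1.43 ± 0.08 SE, 4.12 ± 0.03 to 12.8 ± 0.81 FPKM, SD, n = 2 each, adjusted p = 9.72e-06), Zfp365 (1.4 ± 0.06 SE, adjusted p = 1.71e-06), Mdm2, Trp53inp1 and Ddit4l (1.12 ± 0.09 SE, adjusted p = 8.28e-05). The largest falls after Htatsf1, Stc2 and Chac1 were Ttc32 (-0.77 ± 0.12 SE, adjusted p = 0.00361) and Fam195a (-0.76 ± 0.14 SE, adjusted p = 0.00798). After median-ratio scaling 818 genes rose and 768 fell, so that 51.6% of calls were rises against 63.8% without it. The counts of rises and falls were 430 and 149 without ethanol replicate 1, 319 and 121 without ethanol replicate 2, 451 and 235 without tamoxifen replicate 1, and 563 and 193 without tamoxifen replicate 2.

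The 72 h comparison asked the same question 1 day later. The p53 targets were again higher, with 32 of 39 members rising, 0 falling (33 and 0 adjusted over the list alone) and a median log2 change of 0.72. Mdm2 rose from 57.9 ± 3.10 to 234 ± 0.01 FPKM (SD, n = 2 each), a 4.05-fold ratio of means (2.00 ± 0.06 SE, adjusted p = 7.74e-08). Plk2, a polo-like kinase, rose from 15.0 ± 0.73 to 46.8 ± 0.71 FPKM (1.58 ± 0.07 SE, adjusted p = 3.6e-07). The list passed with the preset correlation (adjusted p = 2.09e-17) and with an estimated correlation (adjusted p = 0.0464). Fibroblast markers were higher in the same libraries: 33 of 34 rose, 0 fell (34 and 0 adjusted over the list alone), and the median was 1.07. Acta2, smooth muscle actin, rose from 36.3 ± 2.37 to 105 ± 0.80 FPKM (1.5 ± 0.06 SE, adjusted p = 3.6e-07). Col1a1 rose from 53.3 ± 2.09 to 123 ± 2.27 FPKM (1.19 ± 0.05 SE, adjusted p = 5.76e-07). That list had an adjusted p = 3.28e-26 with the preset correlation and an adjusted p = 0.171 with an estimated correlation.

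Naive pluripotency genes were lower at 72 h: 12 of 20 fell and 2 rose (13 and 2 adjusted over the list alone), with a median of -0.37, while fibroblast markers rose in the same tamoxifen libraries. Nr5a2, a nuclear receptor of the pluripotency network on chromosome 1 from 138740161 to 138857025, fell from 7.85 ± 0.34 to 3.66 ± 0.08 FPKM (-0.93 ± 0.10 SE, adjusted p = 6.11e-05). Fbxo15 fell from 85.6 ± 1.58 to 54.2 ± 4.10 FPKM (-0.65 ± 0.07 SE, adjusted p = 6.27e-05), and Tbx3 rose as at 48 h (0.48 ± 0.09 SE, adjusted p = 0.00186). Of 13 core pluripotency genes 7 fell and 0 rose (7 and 0 adjusted over the list alone), among them Dnmt3l, a cofactor of DNA methyltransferases (-0.53 ± 0.06 SE, adjusted p = 9.05e-05), and Tdgf1 (-0.47 ± 0.06 SE, adjusted p = 0.000241). The naive list had an adjusted p = 0.000239 and the core list an adjusted p = 0.0414, and with an estimated correlation the adjusted p was 0.171 and 0.28. Formative and primed epiblast genes went both ways, with 8 of 19 higher and 3 lower (8 and 3 adjusted over the list alone, list adjusted p = 0.268). Nodal rose from 31.6 ± 0.14 to 53.2 ± 2.30 FPKM (0.73 ± 0.06 SE, adjusted p = 1.2e-05). Lefty2, an antagonist of Nodal on chromosome 1 from 182823250 to 182829233, fell from 99.4 ± 1.44 to 55.3 ± 0.54 FPKM (-0.84 ± 0.05 SE, adjusted p = 3.07e-06). Sox2 was listed at 0 FPKM in all 8 libraries although its mean of scaled counts in the authors' deposited table was 9365 in ethanol and 7871 in tamoxifen at 72 h, so it was not tested here.

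**Figure D2:**
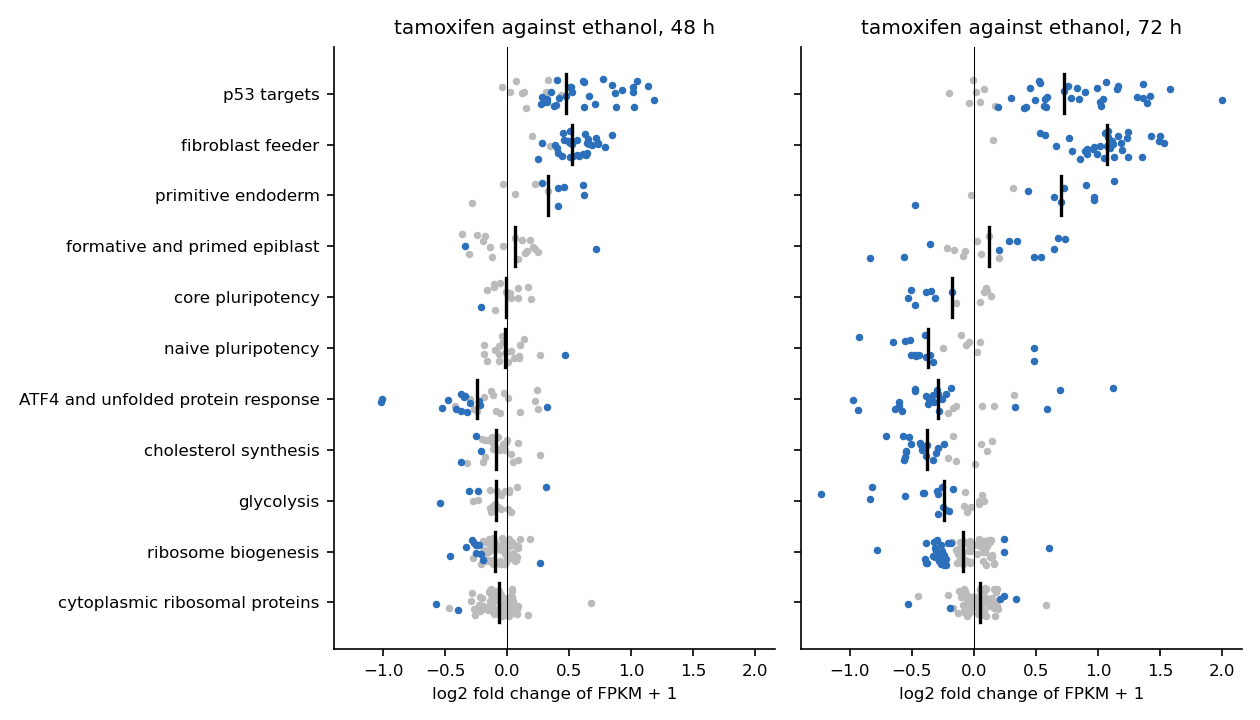
Log2 fold change of FPKM + 1, tamoxifen against ethanol, for each tested member of 11 gene lists at 48 h (left) and 72 h (right). Each point is a gene, blue where its adjusted p was under 0.05, and black bars are list medians. The medians of the p53 targets lay at 0.47 and 0.72, those of the fibroblast markers at 0.52 and 1.07 and those of the naive pluripotency genes at -0.02 and -0.37.

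Cholesterol synthesis genes were lower at 72 h, with 17 of 24 falling and 0 rising (17 and 0 adjusted over the list alone) and a median of -0.38, in the libraries in which fibroblast markers rose by a median of 1.07. From 48 h to 72 h the median of this list was 0.70 in ethanol and 0.35 in tamoxifen. Sqle, squalene epoxidase, fell from 38.1 ± 0.41 to 26.2 ± 0.30 FPKM (-0.52 ± 0.05 SE, adjusted p = 6.43e-05). Insig1, a regulator of sterol synthesis, fell from 46.5 ± 0.78 to 31.6 ± 0.66 FPKM (-0.54 ± 0.07 SE, adjusted p = 0.000159). This list passed with the preset correlation (adjusted p = 1.25e-06) and with an estimated correlation (adjusted p = 0.0464). Glycolysis genes, beside the same rise of fibroblast markers, had 14 of 22 members lower and 0 higher (14 and 0 adjusted over the list alone). Pdk1 fell from 65.6 ± 2.16 to 27.3 ± 0.51 FPKM (-1.23 ± 0.06 SE, adjusted p = 9e-07). Ldhb, a lactate dehydrogenase subunit, fell from 198 ± 1.27 to 112 ± 11.4 FPKM (-0.82 ± 0.07 SE, adjusted p = 1.21e-05). The glycolysis list had an adjusted p = 0.000132 and an adjusted p = 0.288 with an estimated correlation. The glycolysis count was 9 without ethanol replicate 1 and 9 without tamoxifen replicate 2. In the ATF4 and unfolded protein response list, again beside that rise, 19 of 29 fell and 4 rose (19 and 5 adjusted over the list alone, list adjusted p = 0.000179, and an adjusted p = 0.236 with an estimated correlation). Chac1 fell from 19.0 ± 0.21 to 9.17 ± 0.37 FPKM (-0.98 ± 0.07 SE, adjusted p = 4.07e-06). Shmt2, a mitochondrial enzyme of serine metabolism, fell by 0.58 on the log2 scale (SE 0.05, adjusted p = 3.16e-05).

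Ribosome biogenesis genes had 25 of 73 members lower and 3 higher at 72 h (25 and 3 adjusted over the list alone), with a median of -0.09. Dimt1 fell (-0.78 ± 0.09 SE, adjusted p = 0.000146) and Utp20, a processing factor of the small subunit, rose (0.60 ± 0.07 SE, adjusted p = 0.000105). Of 81 cytoplasmic ribosomal protein genes 3 rose, including Rps27l (0.34 ± 0.06 SE, adjusted p = 0.0025), 2 fell, including Rpl22l1 (-0.53 ± 0.08 SE, adjusted p = 0.000513), and 76 did not pass (1 and 1 adjusted over the list alone). Of 75 mitochondrial ribosomal protein genes 22 fell and 4 rose (22 and 4 adjusted over the list alone), Mrps10 at -0.57 ± 0.08 SE (adjusted p = 0.000338) and Mrps9 at -0.49 ± 0.07 SE (adjusted p = 0.000622). The 3 lists had adjusted p = 0.0144, 0.469 and 0.00702, and with an estimated correlation an adjusted p = 0.28, 0.852 and 0.322. Primitive endoderm genes had 8 of 11 members higher and 1 lower (9 and 1 adjusted over the list alone). The list median was 0.71, beside the 1.07 of the fibroblast markers in the same libraries. Col4a1 rose 2.02-fold in ratio of means (0.97 ± 0.06 SE, adjusted p = 3.43e-06) and Sparc by 0.72 ± 0.06 SE (adjusted p = 1.31e-05). The list had an adjusted p = 0.00014 and an adjusted p = 0.192 with an estimated correlation. Without ethanol replicate 2 the ribosome biogenesis count was 15, and with an FPKM of at least 5 required the primitive endoderm count was 5.

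Across the 11867 genes 2380 rose and 2192 fell at 72 h, and 183 rose and 11 fell by at least 2-fold. Il1rl1, on chromosome 1 from 40496494 to 40522259, encodes the receptor of interleukin 33 and rose from 4.73 ± 0.29 to 25.0 ± 1.55 FPKM (SD, n = 2 each, 2.18 ± 0.08 SE, adjusted p = 1.56e-07). Between the times its level in ethanol fell from 18.1 ± 0.08 FPKM (-1.74 ± 0.08 SE, adjusted p = 5.35e-07), while in tamoxifen it stood at 31.9 ± 2.65 FPKM at 48 h. The neighbouring leukotriene B4 receptor genes Ltb4r2 (1.04 ± 0.08 to 8.01 ± 0.43 FPKM, 2.14 ± 0.14 SE, adjusted p = 3.43e-06) and Ltb4r1 (0.386 ± 0.18 to 4.59 ± 0.48 FPKM, 2.02 ± 0.13 SE, adjusted p = 3.18e-06) rose from low levels. Neurod1 rose to 24.6 ± 1.81 FPKM (2.01 ± 0.08 SE, adjusted p = 2.48e-07). The largest falls after Htatsf1 were Pdk1, Enpp3, an ectonucleotidase (40.8 ± 0.09 to 16.8 ± 0.42 FPKM, -1.23 ± 0.08 SE, adjusted p = 4.82e-06), Lrrc34 (15.9 ± 0.24 to 6.29 ± 0.30 FPKM, -1.21 ± 0.13 SE, adjusted p = 6.71e-05) and Pycard, an inflammasome adaptor (15.7 ± 0.42 to 6.30 ± 0.03 FPKM, -1.19 ± 0.10 SE, adjusted p = 1.38e-05). After median-ratio scaling 2169 rose and 2426 fell, after quantile normalization 2249 and 2516, and with an FPKM of at least 5 required 1796 and 1917, so which direction held the majority depended on these choices. Without ethanol replicate 2 the count of genes that fell was 1460.

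Whether the change itself differed between the times was tested as a contrast of the 2 changes. The change was more positive at 72 h for 237 genes and more negative for 172. Ppbp, a platelet chemokine (1.70 ± 0.34 SE, adjusted p = 0.0306), Actg2, a smooth muscle actin (1.43 ± 0.20 SE, adjusted p = 0.00883), and Il1rl1 (1.4 ± 0.11 SE, adjusted p = 0.00138) had the largest positive differences, that of Il1rl1 with a fall of its ethanol level between the times (-1.74). The largest negative ones were those of Gjb1, a connexin (-1.26 ± 0.20 SE, adjusted p = 0.0143), Lrrc34 (-1.15 ± 0.18 SE, adjusted p = 0.0143) and Fuom (-1.10 ± 0.17 SE, adjusted p = 0.0143). The ethanol levels of these 3 rose between the times, by 1.02, 1.57 and 0.94 on the log2 scale (adjusted p = 0.000171, 7.11e-06 and 0.000122). With tamoxifen Gjb1 rose at 48 h (0.57, adjusted p = 0.0247) and fell at 72 h (-0.69, adjusted p = 0.00345), and Fuom rose at 48 h (0.95, adjusted p = 0.00141) and did not pass at 72 h (-0.15, adjusted p = 0.372). Mdm2 rose more at 72 h (difference 0.82 ± 0.08 SE, adjusted p = 0.0045). Of the 20 naive pluripotency genes 7 had a more negative change at 72 h and 0 a more positive one (12 and 1 adjusted over the list alone), Nr5a2 by -0.74 ± 0.14 SE (adjusted p = 0.025). The naive list had an adjusted p = 1.74e-06 for the difference and an adjusted p = 0.133 with an estimated correlation. The p53 list, with 7 of 39 members more positive (9 adjusted over the list alone), had an adjusted p = 9.66e-05, and an adjusted p = 0.149 with an estimated correlation. The fibroblast list, with 19 of 34 more positive (30 adjusted over the list alone), had an adjusted p = 9.46e-25, and an adjusted p = 0.149 with an estimated correlation. The 2 counts, more positive and more negative, were 37 and 13 without ethanol 48 h replicate 1, 41 and 21 without ethanol 48 h replicate 2, 72 and 36 without tamoxifen 48 h replicate 1, and 96 and 100 without tamoxifen 48 h replicate 2. They were 98 and 48 without ethanol 72 h replicate 1, 87 and 40 without ethanol 72 h replicate 2, 160 and 83 without tamoxifen 72 h replicate 1, and 83 and 89 without tamoxifen 72 h replicate 2. Ppbp lost its call without any of 6 of these libraries (adjusted p up to 0.11), and Gjb1, Lrrc34 and Fuom lost theirs without ethanol 48 h replicate 1 (adjusted p = 0.067, 0.0675 and 0.0675). Without the filter on low values all of the 6 but Il1rl1 lost their calls: Ppbp, Actg2, Gjb1, Lrrc34 and Fuom (adjusted p = 0.0944, 0.0562, 0.0513, 0.0674 and 0.0673). Ppbp also did with a pseudocount of 0.1 (adjusted p = 0.0729) and without the trend (adjusted p = 0.057).

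The changes at the 2 times, which use separate control libraries, were then compared. Of the genes that rose at 48 h 811 also rose at 72 h, where independent lists would share 188, and of those that fell 419 also fell, where independent lists would share 98.1. Only 9 genes called at both times changed in opposite directions. Across the 11867 genes Pearson's r of the log2 changes was 0.689 and Spearman's rho 0.636, genes not being independent replicates.

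**Figure D3:**
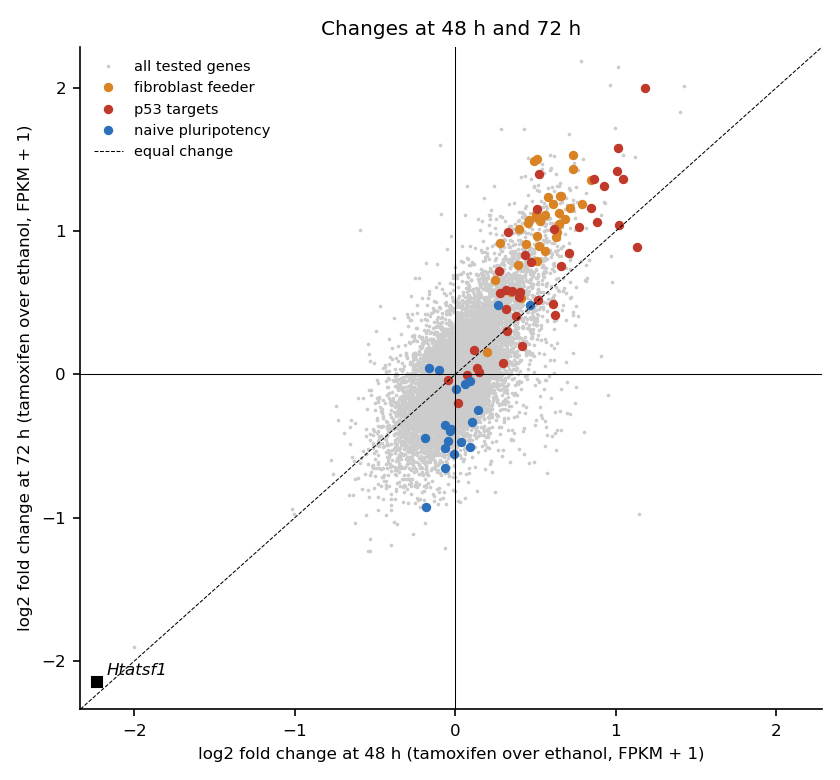
Log2 fold change of FPKM + 1, tamoxifen over ethanol, at 48 h (horizontal) and 72 h (vertical), 1 point for each of 11867 genes, with 3 lists coloured and Htatsf1 as a black square. The dashed line marks equal change. Most fibroblast markers and p53 targets lie in the upper right, at list medians of 0.52 and 1.07 and of 0.47 and 0.72.

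Ethanol libraries at 72 h and 48 h were compared as a background, since time and any day or lane of sequencing are the same split. In ethanol 4506 of 11867 genes were higher and 2278 lower at 72 h, a larger number than tamoxifen gave at either time. Ribosome biogenesis genes were lower over this day (61 of 73, 2 higher, median -0.36, 62 and 2 adjusted over the list alone, adjusted p = 4.29e-21, and an adjusted p = 0.0278 with an estimated correlation). Cholesterol synthesis genes were higher (20 of 24, 1 lower, also adjusted over the list alone, median 0.70, adjusted p = 1.31e-05, and an adjusted p = 0.0465 with an estimated correlation). Spliceosome genes were lower (26 of 47, 3 higher, also adjusted over the list alone, median -0.18, adjusted p = 3.84e-07, and an adjusted p = 0.0278 with an estimated correlation). p53 targets were higher (31 of 39, 2 lower, also adjusted over the list alone, median 0.45, adjusted p = 1.14e-05, and an adjusted p = 0.0963 with an estimated correlation). Of the fibroblast markers 6 were higher and 13 lower (adjusted p = 0.0551). Median-ratio scaling moved the median of all genes in this contrast by -0.12 on the log2 scale and gave 3343 higher and 3371 lower genes, 49.8% higher against 66.4% without it. After quantile normalization 3073 were higher and 3226 lower, 48.8% higher. Mdm2 differed by 0.24 ± 0.06 SE between the ethanol groups (adjusted p = 0.00585), against 2.00 for tamoxifen at 72 h. Trp53inp1 differed by 1.13 ± 0.06 SE between them (limma adjusted p = 7.24e-07), against 1.13 for tamoxifen at 48 h and 0.89 at 72 h. The p53 list median of 0.45 in ethanol over time stood beside 0.47 and 0.72 for tamoxifen at 48 h and 72 h.

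The authors' deposited tables of the same comparisons hold 16729 genes at 48 h and 17011 at 72 h. With the sign set to tamoxifen over ethanol, the authors' deposited table listed 1107 genes higher and 888 lower at 48 h, and 2807 higher and 2643 lower at 72 h, at an adjusted p of 0.05. Of the 1465 limma calls at 48 h that have a row in the authors' deposited table, 1218 were called there in the same direction and 0 in the opposite one, and at 72 h 4054 of 4571 and 0. For Htatsf1 the authors' deposited table gave log2 changes of -2.48 at 48 h and -2.43 at 72 h, for Mdm2 1.17 and 1.99, and for Nr5a2 -0.17 and -1.23.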

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

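The tests of p53 targets against the fibroblast markers, of scaling, of tamoxifen itself, of dilution and of a delay were chosen after the results were seen, and the test on Y-linked genes before.

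The change was more positive at 72 h for 237 genes and more negative for 172. Single genes stood out by differences of 1.70 for Ppbp, 1.43 for Actg2 and 1.4 for Il1rl1, whose ethanol level fell between the times (-1.74), and of -1.26 for Gjb1, -1.15 for Lrrc34 and -1.10 for Fuom, whose ethanol levels rose (1.02, 1.57 and 0.94), on the log2 scale. The lists past the preset set test had median differences of 0.50 for fibroblast markers, 0.35 for primitive endoderm, 0.17 for p53 targets, 0.11 for cytoplasmic ribosomal proteins, -0.12 for cell cycle, -0.15 for core pluripotency, -0.15 for glycolysis, -0.31 for cholesterol synthesis and -0.36 for naive pluripotency. No list passed for the difference with an estimated correlation, the smallest adjusted p being 0.0968 for cholesterol synthesis.

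Fibroblast markers were higher with tamoxifen at 72 h, by a median of 1.07. A difference in scaling between libraries was argued against by the size of the shift, as median-ratio scaling moved changes at 72 h by a median of only -0.02. With so small a shift, 33 of 34 members still rose after it. A larger share of feeder cells in the tamoxifen cultures may account for the rise: the median log2 change of 4 Y-linked genes, taken as feeder genes since Eif2s3y stood at 0.00177 of Eif2s3x in ethanol, was 0.125, under the bound of 0.3 written beforehand to argue against it. That bound was a poor one, as was seen after the levels were known, since no Y-linked gene exceeded 0.606 FPKM, log2(FPKM + 1) compresses such values (Ddx3y stood at 211% and Eif2s3y at 173% of ethanol in FPKM, with log2 changes of 0.19 each, while Uty stood at 0.06 and Kdm5d at -0.12), and the sex of the feeders is not in the labels, so the test decides nothing. Thbs1 at 275 FPKM and Lgals1 at 202 rose, Fn1 at 203 did not pass (0.16), and changes within feeder or stem cells, which were not measured apart, stay open.

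p53 targets were higher with tamoxifen at both times, beside the rise of fibroblast markers. They were also higher in ethanol at 72 h than at 48 h, by a median of 0.45 against 0.47 and 0.72 for tamoxifen at 48 h and 72 h. A larger feeder share raises no gene by more than a gene that feeders alone express. At 48 h 9 targets exceeded the upper quartile of the fibroblast list (0.65) by more than 2 SE. Only 6 exceeded every fibroblast marker (highest 0.84) by as much: Mdm2, Trp53inp1, Btg2, Phlda3, Plk2 and Perp. The SE is that of the target alone here and at 72 h, and the error of the marker was not counted. The excess argues against a larger feeder share as the whole cause at 48 h for Mdm2 (1.18) and Trp53inp1 (1.13). Btg2, Phlda3, Plk2 and Perp (1.01 to 1.04) lay too close to the highest marker to decide it. At 72 h Mdm2 was the 1 target above every marker (highest 1.53) by more than 2 SE. There 6 exceeded the upper quartile (1.19) by as much, and 7 passed above the median (1.07) by limma. Trp53inp1 (0.89) and Phlda3 (1.04) lay below that median. For the other targets and for most at 72 h a larger share may account for the rise. Tamoxifen or the activated recombinase cannot be told apart from the loss of Htatsf1, because 0 libraries of cells given tamoxifen kept the gene. The loss of Htatsf1 stays open as a hypothesis.

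Naive pluripotency genes were lower with tamoxifen at 72 h (median -0.37). Dilution of stem cell RNA by feeder RNA lowers all stem cell genes alike. Of 13 core pluripotency genes 7 lay above the naive median by more than 2 SE, Pou5f1 at 0.10, Utf1 at 0.11 and Dppa2 at 0.14 among them. Yet 7 of the 13 were called lower and 0 higher. Part of the naive list also lies above its own median, so this count does not set core genes apart from naive ones. Changes ranged from -0.93 to 0.48 in the naive list and from -0.53 to 0.14 in the core list. That spread argues against dilution as the whole cause. A delay of the tamoxifen cultures leaves each change from 48 h to 72 h between 0 and that in ethanol, if levels move steadily, but 5 of 20 naive genes lay outside by more than 2 SE: Nr5a2 (0.34 in ethanol, -0.40 in tamoxifen), Zfp42 (0.19 and -0.23), Klf2 (0.06 and -0.49), Fgf4 (-0.07 and -0.44) and Nr0b1 (-0.43 and -0.93), 6 after median-ratio scaling and 5 after quantile normalization. This argues against a delay as the whole cause, though 9 of the 15 naive genes with a called ethanol change moved the same way by less with tamoxifen and a delay could contribute to those. All 5 genes outside lay below the interval, the direction in which dilution acts, and a delay together with dilution was not tested. An effect of losing Htatsf1 on the naive genes stays open.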

How the results depend on the processing

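The comparison with the fibroblast median and every alternative of the list counts were chosen after seeing the data. Htatsf1 kept its direction and call under all alternatives, from -2.29 to -2.08 when single libraries were left out. A lone remaining library was assumed to vary like the other groups. The cause was not tested for any change below, except where fewer libraries or a stricter threshold made it. With at least 2-fold required, the counts of rises and falls were 13 and 3 at 48 h, 183 and 11 at 72 h, 13 and 5 for the difference and 309 and 68 in ethanol over time. Without a filter on low values 308 genes fell at 48 h, and the difference had 31 and 13. Without the trend the difference had 148 and 78. Tested against the fibroblast median (0.52 at 48 h and 1.07 at 72 h) in place of 0, 49 genes passed above it at 48 h and 49 at 72 h. Against 0 the rises numbered 935 and 2380, so most were not set apart from a rise of that size. With 1 library left out the counts ran from 319 to 961 rises and 121 to 622 falls at 48 h, 1800 to 2334 and 1460 to 2172 at 72 h, 37 to 160 and 13 to 100 for the difference, and 3525 to 4523 and 1704 to 2338 in ethanol. The labels give only shared replicate numbers and do not say that they mark a pair, and deviations of same-numbered libraries correlated at 0.00 at 48 h and -0.06 at 72 h. A replicate block across all 8 libraries gave 844 and 441 at 48 h, 2310 and 2099 at 72 h and 158 and 108 for the difference, and a replicate block within each time point gave 133 and 79 for the difference and 1 cholesterol synthesis gene lower at 48 h. With these 2 blocks Tdgf1 (adjusted p = 0.0706 and 0.064), Krt8 (0.0659 and 0.0715) and Acat2 (0.0508 and 0.0516) did not pass at 48 h. No named gene and no list past camera changed direction, but list medians near 0 changed sign under a scaling: at 48 h core pluripotency, spliceosome, translation factors, cell cycle and neighbours of Htatsf1, and in ethanol over time fibroblast markers (0.01 to -0.11 and -0.16), glycolysis, ATF4, cell cycle, 2-cell-like genes and neighbours of Htatsf1. So did translation factors and neighbours of Htatsf1 at 72 h, and neuroectoderm, ribosome biogenesis and snoRNA host genes for the difference. Of named-gene results 760 were the same under alternatives other than leave-one-out, 70 lost and 1 gained a call, and of list results 118 were the same and 38 lost the call, 33 of them with an estimated correlation. Depth limits low genes most: tamoxifen 48 h replicate 1 had 8.99 M implied fragments.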

Other observations

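Of the lists not described above for tamoxifen against ethanol, the cell cycle list had 4 of 40 members lower and 3 higher at 48 h (adjusted p = 0.892) and 15 lower and 5 higher at 72 h (adjusted p = 0.0756). Spliceosome genes, the class that includes the partners of HTATSF1 in the U2 snRNP, had 6 of 47 higher and 3 lower at 48 h (adjusted p = 0.72) and 13 higher and 7 lower at 72 h (adjusted p = 0.273). Translation factors had 0 of 34 higher and 2 lower at 48 h (adjusted p = 0.18) and 8 higher and 5 lower at 72 h (adjusted p = 0.634), the host genes of small nucleolar RNAs 1 of 14 lower at 48 h (adjusted p = 0.121) and 1 higher and 3 lower at 72 h (adjusted p = 0.469). Only 14 of the 24 listed host genes had an entry in the files, 9 of them also members of other lists, and the noncoding hosts such as Gas5 and the Snhg genes were not among them. Primitive streak and mesoderm genes had 4 tested members, of which 1 (Wnt3) rose at 48 h and 2 (Wnt3 and Hand1) at 72 h (adjusted p = 0.224 and 0.23). Of 2 tested genes of the 2-cell-like list, Zfp750 rose at both times (0.99 and 1.72) and Eif1a fell at 72 h (-0.28), with list adjusted p = 0.366 and 0.605. At 72 h the trophoblast list had 5 of 11 higher and 1 lower (adjusted p = 0.24) and the neuroectoderm list 1 of 7 higher and 3 lower (adjusted p = 0.184).

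The genes that follow were picked after their values were seen. Ddit3 and, in ethanol over time, Nanog moved against their lists, while Trp53 and Gm20594 belong to none. Ddit3, a stress-induced transcription factor, rose at 72 h (1.12) while 19 members of the ATF4 and unfolded protein response list fell, and its log2 change at 48 h was -0.09. Nanog was higher at 72 h than at 48 h in ethanol (1.13), where 9 of 13 core pluripotency genes were lower. At 72 h it was lower with tamoxifen, as its list was, at 103 FPKM against 147 in ethanol (-0.51). The mRNA of p53 itself, Trp53, stood at 116% of ethanol at 48 h and 122% at 72 h. Gm20594 ranged from 833 to 3284 FPKM over the 8 libraries. Its group means were 985 ± 215 FPKM in ethanol and 2198 ± 623 FPKM in tamoxifen at 48 h (SD, n = 2 each). At 72 h they were 3132 ± 215 FPKM in ethanol and 1609 ± 331 FPKM in tamoxifen.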
